A study of Homo sapiens with 6 samples.

How the data were processed

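RNA of the human renal carcinoma cell line SN12C was measured on 6 Illumina bead arrays, 3 of control cells and 3 of cells with short hairpin RNAs (shRNAs) against YAP and TAZ. Per the labels, total RNA was extracted from frozen cell pellets, reverse transcribed and transcribed in vitro into biotin-labelled cRNA. The series describes the 3 arrays of an arm as technical repeats, so every p-value below measures technical spread between arrays and not the spread between cultures. Arrays were assigned to their arm by the YAP/TAZ status in the labels. Choices of test, probe filter, gene lists, named genes and alternative settings were made before the data were examined, except where the text says otherwise.

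The deposited table of probe intensity gives the average brightness of each probe on a linear scale, per the file headers without normalization, together with a detection p-value for each probe and array, per the file headers. It held 48202 lines, of which 887 at its end carried no probe identifier and were left out, leaving 47315 probes. A second deposited table holds log2 values made by the authors. The submitters' processing notes name limma and give no version, and the exact steps and the scanner software are not given in the sources used here. The deposited log2 table held 20348 probes, and these were exactly the probes with a detection p-value under 0.05 on at least 3 of the 6 arrays. Its values differed from the normalized values computed here by a median of 0.000186 and by at most 0.0238 on the log2 scale, so its scale was log2, uncentred. The medians of its 6 columns were 6.261, 6.262, 6.262, 6.257, 6.262 and 6.262. Columns were assigned to arrays by name, and each deposited log2 column correlated best with the raw column of the same array. No slide is named in the files, and no genome build is given in the sources used here, so no coordinates are printed.

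Intensities were background-corrected by normexp using the detection p-values, with an offset of 16, quantile-normalized and brought to log2 (neqc of limma 3.58.1 in R 4.3.3). Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were kept. Gene symbols came from the platform annotation supplied with the data. It listed 15497 of the kept probes, 15493 with 1 symbol and 4 with several, and 4851 kept probes were unnamed in it. Of the probes with 1 symbol, 15484 were matched through their Entrez identifier to a current human gene table, and 0 symbols changed. Each gene was represented by its probe with the highest mean intensity over the 6 arrays, which gave 11646 genes, 3072 of them with more than 1 kept probe. Detection on an array depended on the brightness of a probe over the array's background: 41.6% to 44.3% of the probes were detected per array. The number of arrays limits the precision.

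The arms were compared with lmFit and eBayes of limma, with the group as the only term, and p-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called changed at an adjusted p under 0.05. Errors of log2 changes are the standard errors (SE) of that fit, and errors of intensities are standard deviations (SD) of 3 arrays. A probe detected on 0 of the 3 arrays of an arm gave only a bound there. Its change is written as "at least N-fold", from the bright arm's mean log2 intensity and, for each array of the dim arm, the higher of the probe's own value and the lowest value among detected probes. A log2 change printed beside such a bound is the fitted value and is not itself a bound.

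The 30 gene lists, with 723 distinct genes of which 583 were tested, were fixed in advance. They were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the 30 lists. Camera with a correlation estimated for each list, and fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, were run as alternatives. The genes named in the text were YAP1 and WWTR1, the 12 largest rises and the 12 largest falls, and up to 4 members of each list with the largest changes. The rises and falls were taken among called genes with no overlap between the arms, detected on the 3 arrays of the higher arm and with a symbol that is not a placeholder. This rule gave 138 genes. Other list members are named where a count is described, and genes named in the closing section outside the rule were chosen after their values were seen. For 48 of the 138 genes more than 1 probe was kept. Another probe gave the opposite sign for 1 of them (GCLM) and missed the threshold with the same sign for 10 (BID, CALD1, CPT1A, DDR1, GABARAPL2, MUC1, SLC5A12, SYVN1, TNFRSF10B and TPM1).

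The labels number the arrays 1 to 3 in both arms. Deviations from the arm's mean over the 11646 genes correlated at 0.627 between the arrays numbered 1, 0.27 between those numbered 2 and 0.467 between those numbered 3. All 3 lie above 0.1, the limit set for taking the numbers as pairs. However, knockdown array 2 correlated more with control array 3, at 0.378, and knockdown array 3 with control array 2 at 0.222. Deviations from an arm's mean cancel within the arm, so a pattern shared by the arrays numbered 1 makes the others correlate too. Passing the limit therefore does not tell pairs apart among the arrays numbered 2 and 3. The pairing rests on these values, because the labels do not say what the number marks. The fit with the number as a block was run as an alternative.

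Alternatives were no background correction, normexp on the intensities alone with an offset of 50, median scaling in place of quantile normalization, the authors' deposited log2 values, no filter on dim probes, and a detection p-value under 0.01 on all 6 arrays. Others were the mean of a gene's probes, each kept probe by itself, an intensity trend with a robust prior, the replicate block, and leaving out each array in turn. The fit was tested on simulated arrays of 3 against 3 with the means and spreads of the 11646 real genes and 200 changed genes. It recovered 26.9% of the genes changed by 0.5 on the log2 scale, 98.5% of those changed by 1 and 97.0% of those changed by 2, and 9 of 171 calls (5.26%) were false. The shifted list was called and 0 others were. Genes were simulated independently of each other, so this does not test list calls where the genes of a list vary together. A far smaller share of genes changed than in the real comparison, so the adjusted threshold was stricter. The shares recovered hold for that simulation alone.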

Results

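The series asks, by its title, how metabolism and signalling shift in tumor cells that lack NF2 when YAP and TAZ are inhibited. NF2 encodes merlin, an upstream activator of the Hippo kinases, and YAP and TAZ are the transcriptional co-activators which those kinases restrain. SN12C cells with a control vector were compared with SN12C cells carrying inducible shRNAs against both genes, on 3 arrays each. All cells received doxycycline, which switches the shRNAs on, for 3 days or longer, and were kept without serum during the last 24 hours. Between 19674 and 20971 of 47315 probes were detected per array. The median raw intensity was 87.6, 102.4 and 90.9 on the control arrays and 98.7, 91.4 and 90.4 on the knockdown arrays. Across genes, which are not independent replicates, log intensities correlated at 0.983 or above within each arm and at 0.955 or below between arms.

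YAP1 RNA was 2.86-fold lower in the knockdown arm. Its log2 intensity was 8.40 ± 0.121 (SD, n = 3) in control cells and 6.89 ± 0.401 (SD, n = 3) in knockdown cells, a log2 change of -1.51 ± 0.19 (SE) with an adjusted p of 0.000355 in limma. The control arrays gave 8.47, 8.26 and 8.47 and the knockdown arrays 7.33, 6.77 and 6.56, so the arms did not overlap. YAP1 had 1 tested probe. WWTR1, which encodes TAZ, had no kept probe assigned to it alone in the annotation, so the knockdown of TAZ was not checked in these arrays.

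Among 20 measured genes known as direct targets of YAP/TAZ with TEAD transcription factors, 6 fell, 3 rose and 11 did not pass the threshold, and the same counts held adjusted over the list alone. The largest falls were in CCN1 (6.67-fold) and CCN2 (1.94-fold), which encode secreted matricellular proteins, in IGFBP3 (6.02-fold), an insulin-like growth factor binding protein, and in ANKRD1 (at least 3.31-fold), which was not above background on the knockdown arrays and fell 1.65-fold without background correction. AXL and CCDC80 also fell. MYOF, GADD45A and NT5E rose, by 0.41, 0.44 and 0.59 on the log2 scale. GADD45A missed the threshold with median scaling (adjusted p = 0.0829), without control array 1 (0.0663), without knockdown array 2 (0.0768) and without knockdown array 3 (0.0734). The median log2 change of the list was -0.20, and as a list it did not pass camera (adjusted p = 0.0591, and 0.316 with an estimated correlation). Median scaling alone brought it past the threshold (0.0421, within a range of 0.0421 to 0.162 over the settings with a preset correlation), and fry gave an adjusted p of 0.000158.

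**Figure D1:**
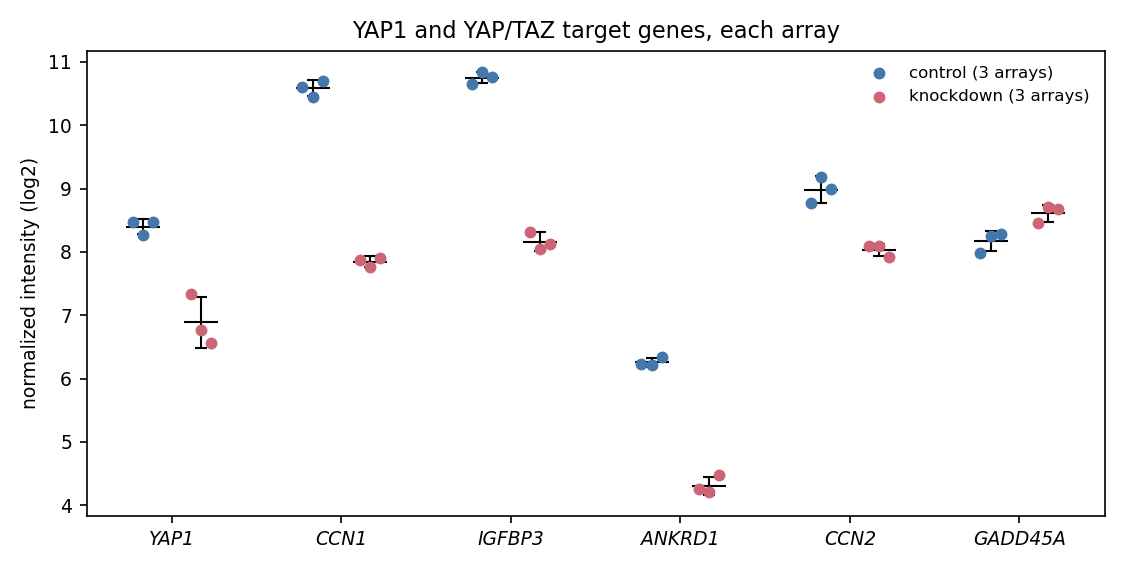
Normalized log2 intensity of YAP1 and 5 YAP/TAZ target genes on each array, with control arrays in blue and knockdown arrays in red, and horizontal bars and whiskers for the mean and SD of 3 arrays. YAP1 stood at 8.40 in control and 6.89 in knockdown cells, and CCN1 at 10.6 and 7.85.

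Components of the Hippo pathway itself also differed between the arms. Of 14 measured genes, 6 were lower and 2 higher, also adjusted over the list alone. The 6 include YAP1, itself targeted by the shRNAs, and the list was not tested without it. FRMD6 (3.67-fold) and WWC1 (2.92-fold), both scaffolds upstream of the Hippo kinases, fell together with YAP1, TEAD4, NF2 and MOB1A. TEAD2 rose 2.66-fold, and STK3 rose by 0.46 on the log2 scale. The list as a whole did not pass camera (adjusted p = 0.134), and fry gave an adjusted p of 0.00277.

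Beyond the targeted pathway, 4638 of 11646 genes (39.8%) changed, 2369 higher and 2269 lower in knockdown cells, and 976 of them (8.38%) by at least 1 on the log2 scale, 416 higher and 560 lower. With genes not detected in an arm at their bound, 949 changed by that much, 405 higher and 544 lower. At an unadjusted p under 0.05 there were 5575. The arms did not overlap for 50.9% of the genes, against 10% by chance. COL3A1, which encodes a fibrillar collagen, rose 124.8-fold, from 5.08 ± 0.199 to 12.05 ± 0.0634 (SD, n = 3; adjusted p = 2.47e-08). BMP5, a bone morphogenetic protein, rose at least 37.7-fold and AKR1C3, an aldo-keto reductase, at least 14.1-fold, both from below background. S100A4, a calcium-binding protein, rose 14.2-fold, AGTR1, the angiotensin receptor, 11.6-fold, and PCOLCE, an enhancer of procollagen processing, 9.93-fold. TMEFF2, SPRY1, CA11, GASK1B, PTPRD and TPD52L1 completed the 12 largest rises, with log2 changes of 2.94 to 3.22, of which that of PTPRD, at least 6.85-fold, started below background. The count of genes changed by at least 1 on the log2 scale was 378 without background correction and 511 with normexp on the intensities alone. Of 138 called genes named by the rule, the fitted fold was smaller by over 1.5 times for 42 without background correction and for 31 with normexp on the intensities alone. COL3A1 rose 39.6-fold and 54.8-fold in these settings, BMP5 9.91-fold and 14.2-fold, and AKR1C3 4.18-fold and 5.69-fold, so a fold given as at least some value holds for the planned background correction alone. Without background correction the other rises were 8.01-fold for S100A4, 5.96-fold for PCOLCE, 5.56-fold for TMEFF2, 4.56-fold for CA11, 3.89-fold for GASK1B, 3.77-fold for SPRY1, 3.62-fold for AGTR1, 3.24-fold for TPD52L1 and 2.60-fold for PTPRD. With the mean of the probes of a gene, the fitted fold was smaller by over 1.5 times for CALD1 (3.32-fold), ERBB3 (3.87-fold), SNAI2 (6.63-fold), SPRY4 (2.43-fold), UBASH3B (5.34-fold) and EVA1A (11.3-fold).

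The largest falls were in ARMCX2 (36.8-fold), from 10.01 ± 0.0938 to 4.81 ± 0.161 (SD, n = 3; adjusted p = 5.38e-08), and in SERPINE2 (25.5-fold), a secreted protease inhibitor. PHGDH, the enzyme that opens serine synthesis, fell at least 21.5-fold, and EVA1A at least 21.0-fold, both to below background. CPA4, PXDN, MIF, SFRP1, CRIP1, PDLIM1, UBASH3B and FSCN1 followed, with falls of 22.7-fold for CPA4, a carboxypeptidase, down to 13.7-fold for FSCN1, which encodes the actin-bundling protein fascin. In the settings without background correction and with normexp on the intensities alone, ARMCX2 fell 10.7-fold and 14.8-fold, SERPINE2 9.10-fold and 12.1-fold, PHGDH 5.98-fold and 8.40-fold, and EVA1A 6.05-fold and 8.61-fold. Without background correction the falls were 13.9-fold for CPA4, 8.85-fold for CRIP1, 8.19-fold for PDLIM1, 7.42-fold for MIF, 7.38-fold for PXDN, 4.83-fold for SFRP1 and 4.20-fold for UBASH3B. Of all genes, 130 were detected on the 3 knockdown arrays and on 0 control arrays, and 176 the other way round.

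**Figure D2:**
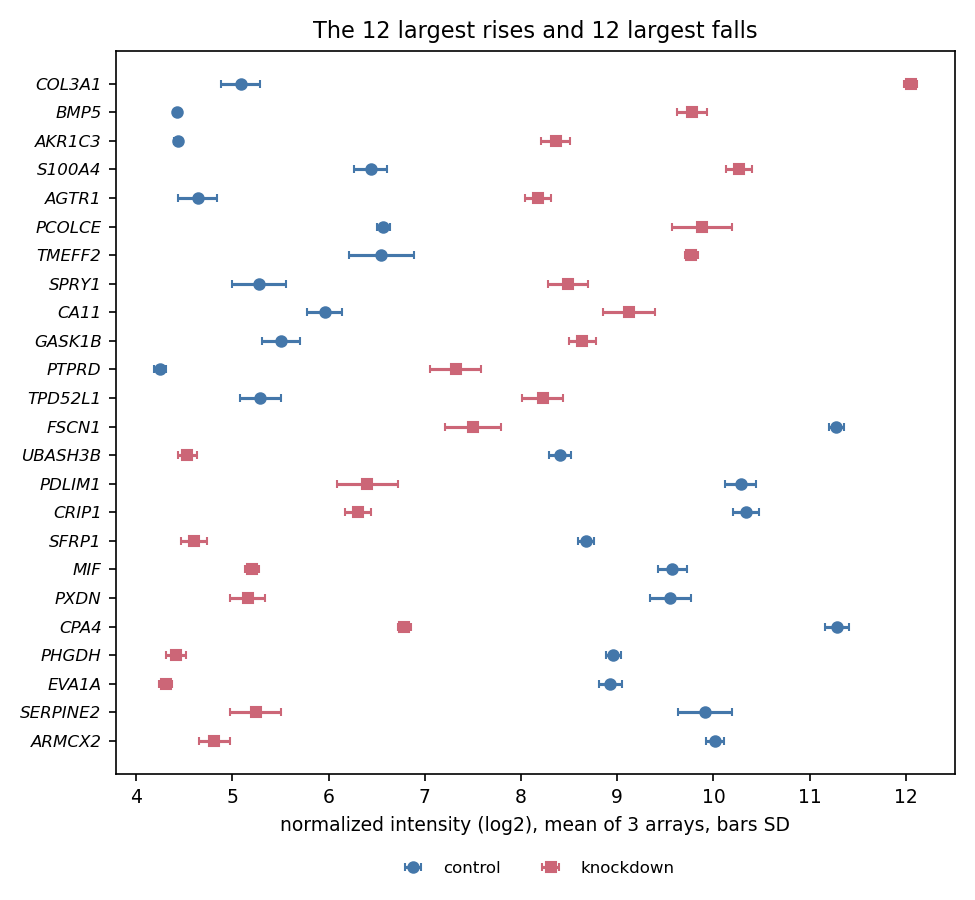
Mean normalized log2 intensity in control cells (blue circles) and knockdown cells (red squares) of the 12 genes with the largest rise and the 12 with the largest fall, with SD of 3 arrays as bars. The widest gap is that of COL3A1, with means of 5.08 and 12.05.

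Genes of mitosis were lower throughout. All 30 measured members fell, also adjusted over the list alone, with a median log2 change of -1.59 (camera adjusted p = 1.15e-15, and adjusted p = 0.389 with an estimated correlation). KIF20A, a kinesin of cytokinesis, fell 7.26-fold, CCNB2, a mitotic cyclin, 5.79-fold, AURKB, a kinase of chromosome segregation, 5.29-fold, and DLGAP5, a spindle protein, 4.81-fold. Without background correction KIF20A fell 4.14-fold, DLGAP5 3.12-fold and AURKB 2.97-fold. Genes of DNA replication and S phase gave a median of -0.20, with 8 of 29 lower, 0 higher and 5 lower adjusted over the list alone. UHRF1 fell 2.10-fold and CDT1, a replication licensing factor, 2.00-fold. MCM2 (-0.13) and MCM3 (0.01) on the log2 scale did not pass. This list missed the threshold (adjusted p = 0.0508, and 0.707 with an estimated correlation) but passed it with the replicate number as a block (0.0262), within a range of 0.00334 to 0.17 over settings with a preset correlation. It also passed without control array 1 (0.0353), without control array 3 (0.0496) and without knockdown array 2 (0.00334), and with median scaling (0.0483) or the mean of probes (0.0418).

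Listed cholesterol synthesis genes fell in 14 of 17 measured cases, also adjusted over the list alone, with 0 higher. Their median log2 change was -1.01 (camera adjusted p = 3.36e-06, and adjusted p = 0.31 with an estimated correlation). The list does not hold the whole pathway. Outside it TM7SF2, a sterol reductase, rose by 2.13 on the log2 scale and ACAT2 fell by 2.27, both picked after their values were seen. EBP, a sterol isomerase, fell 3.41-fold, HMGCS1, which makes the precursor of mevalonate, 3.23-fold, IDI1 2.65-fold and FDPS 2.62-fold. SREBF2, the transcription factor of the pathway, changed by 0.24 on the log2 scale and did not pass. Fatty acid synthesis was mixed, with 7 of 19 lower and 2 higher, also adjusted over the list alone, and a median of -0.28 (camera adjusted p = 0.0453, and adjusted p = 0.316 with an estimated correlation). FASN, the fatty acid synthase, fell 2.56-fold, ACLY 2.08-fold and LPIN1 2.06-fold, while SREBF1, a transcription factor of lipid synthesis, rose 2.19-fold. FASN missed the threshold with an intensity trend and robust prior (adjusted p = 0.0533, the highest over its settings). The call of the fatty acid synthesis list ended without control array 2 (0.0616), control array 3 (0.0524), knockdown array 2 (0.0971) or knockdown array 3 (0.0607), and under the stricter detection filter (0.0841), within a range of 0.0174 to 0.0971.

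Amino acid stress genes, known targets of ATF4, were lower in 15 of 22 cases and higher in 1, with 15 and 2 adjusted over the list alone. Their median log2 change was -0.80, or -0.735 with genes below background set at their bound, and the camera adjusted p was 1.73e-05 (adjusted p = 0.31 with an estimated correlation). Besides PHGDH, the falls included SLC7A5, an importer of large neutral amino acids (6.11-fold), ATF3, a stress-induced transcription factor (3.87-fold, or 2.23-fold without background correction), and ASNS, asparagine synthetase (3.10-fold). PSAT1 and PSPH, the next enzymes of serine synthesis, fell by 1.35 and 0.95 on the log2 scale. SLC3A2, the partner of SLC7A5, rose by 0.28. Glutamine and nucleotide synthesis genes fell in 10 of 22 cases and rose in 1, also adjusted over the list alone, with a median of -0.23 (camera adjusted p = 0.0114, and adjusted p = 0.45 with an estimated correlation). TYMS, thymidylate synthase, fell 2.34-fold, CTPS1, CTP synthase, 2.27-fold, and PFAS, an enzyme of purine synthesis, 1.98-fold.

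In central carbon metabolism most called members fell. Over all genes tested 39.8% were called, 2369 higher and 2269 lower. Of 21 glycolysis and glucose uptake genes, 9 fell and 3 rose, 10 and 4 adjusted over the list alone, with a median of -0.29 (camera adjusted p = 0.0229, and adjusted p = 0.435 with an estimated correlation). PFKP, a phosphofructokinase, fell 3.06-fold, PFKFB4 2.03-fold and HK1, a hexokinase, 1.81-fold, whereas the glucose transporter SLC2A1 rose by 0.73 on the log2 scale and SLC2A3 fell by 0.78. Of 21 genes of pyruvate entry and the TCA cycle, 7 fell and 1 rose, 4 and 1 adjusted over the list alone, with a median of -0.26 (camera adjusted p = 0.0227, and adjusted p = 0.707 with an estimated correlation). MPC1, a subunit of the mitochondrial pyruvate carrier, fell 2.04-fold, and PDHA1 and PDHB, subunits of pyruvate dehydrogenase, 1.63-fold and 1.5-fold, while PDK2, a kinase that inhibits that enzyme, rose 1.66-fold. Of 47 genes of the respiratory chain and ATP synthase, 9 fell, 1 rose and 37 did not pass, a smaller share called than over all genes. Adjusted over the list alone 6 fell and 0 rose. The median was -0.12 (camera adjusted p = 0.0442, and adjusted p = 0.707 with an estimated correlation). The complex I genes NDUFA9 and NDUFS4 fell 1.79-fold and 1.55-fold. Without knockdown array 1 these calls ended for glycolysis (0.0566, within 0.0112 to 0.0566), pyruvate and TCA (0.103, within 0.00793 to 0.103) and the respiratory chain (0.17, within 0.00443 to 0.17). The respiratory chain also missed the threshold without control array 3 (0.0606) and without knockdown array 2 (0.0516), and fry called neither of the last pair (0.0647 and 0.0878). Without both arrays numbered 1, a setting chosen after the data were seen, the calls of pyruvate and TCA (0.0526) and the respiratory chain (0.0985) ended too.

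Mitochondrial ribosome and biogenesis genes were lower in 4 of 22 cases, 1 adjusted over the list alone, and higher in 0. The share called was below the 39.8% of all genes. MRPL19 fell 1.76-fold. The list did not pass (adjusted p = 0.0987) except without control array 2 (0.0452) and without background correction (0.0408), within a range of 0.0408 to 0.198. Fatty acid oxidation genes went both ways, with 4 of 17 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.776). SLC25A20, the carnitine carrier, rose 1.78-fold and ECI2 fell 1.82-fold.

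Genes known as output of the ERK pathway rose. Of 17 measured members 11 were higher and 0 lower, also adjusted over the list alone, with a median log2 change of 0.89 (camera adjusted p = 1.92e-05, and adjusted p = 0.222 with an estimated correlation). SPRY1 rose 9.26-fold and SPRY4 4.21-fold, both encoding feedback inhibitors of receptor tyrosine kinase signalling, EGR1, an immediate early transcription factor, 3.88-fold, and PHLDA1 3.38-fold. Without background correction SPRY1 rose 3.77-fold, EGR1 2.19-fold and SPRY4 1.81-fold, and with normexp on the intensities alone 4.80-fold, 2.57-fold and 2.16-fold. CCND1, the G1 cyclin D1, rose by 1.49 on the log2 scale. DUSP6 (-0.06), FOSL1 (-0.24) and MYC (0.12) did not pass. Receptor tyrosine kinases themselves went both ways, with 4 of 19 higher and 7 lower, 6 and 7 adjusted over the list alone (camera adjusted p = 0.335). ERBB3 fell 11-fold, ROR2 at least 2.39-fold to below background (1.46-fold without background correction) and PDGFRB 2.29-fold.

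Lysosomal genes were higher in 19 of 29 cases and lower in 1, with 21 and 1 adjusted over the list alone, and a median log2 change of 0.61 (camera adjusted p = 4.87e-05, and adjusted p = 0.31 with an estimated correlation). GAA, acid alpha-glucosidase, rose 3.61-fold (2.02-fold without background correction), CTSA, cathepsin A, 2.97-fold, SGSH 2.27-fold and TPP1 2.17-fold. NPC1, a lysosomal cholesterol exporter, fell by 1.10 on the log2 scale. Autophagy genes gave 5 of 22 higher and 2 lower, also adjusted over the list alone, a smaller share called than the 39.8% of all genes. The autophagy list did not pass camera (adjusted p = 0.227). ULK1, a kinase that starts autophagy, rose 1.68-fold and ATG7 fell 1.54-fold.

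Genes of the actin cytoskeleton and targets of the transcription factor SRF fell in 13 of 20 cases, also adjusted over the list alone, with 0 higher and a median log2 change of -0.54 (camera adjusted p = 8.55e-06, and adjusted p = 0.316 with an estimated correlation). TAGLN2 fell 6.58-fold, TPM1, a tropomyosin, 3.64-fold and FHL2 3.52-fold, while ACTG1 (-0.05) and SRF (-0.08) did not pass. CALD1, caldesmon, fell at least 9.37-fold by its brightest probe, and another kept probe of CALD1 gave -0.02. It fell 3.15-fold without background correction, 4.24-fold with normexp on the intensities alone and 3.32-fold with the mean of its probes. Without any 1 of the control arrays the brightest probe left the filter, and CALD1 was then -0.13, 0.02 and 0.04 without control array 1, 2 and 3, none past the threshold. Extracellular matrix and integrin genes went both ways, with 11 of 27 lower and 6 higher, also adjusted over the list alone (camera adjusted p = 0.218). TNC, tenascin C, fell 6.91-fold (4.33-fold without background correction), TGFBI 5.81-fold and COL4A1 4.08-fold, against the rise of COL3A1.

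Lists of cell state markers were not called by camera with the preset correlation in limma. Epithelial markers gave 3 of 9 lower and 1 higher, also adjusted over the list alone, and KRT19, a keratin, fell 8.28-fold and CLDN1, a claudin, 2.42-fold. That list did not pass (adjusted p = 0.0788) except without control array 1 (0.048), without control array 2 (0.0395), under the stricter detection filter (0.0281) and with the mean of probes (0.0418), within a range of 0.0281 to 0.0902 over settings with a preset correlation, and fry called it (0.0015). Mesenchymal markers gave 4 of 10 higher and 4 lower, 4 and 6 adjusted over the list alone (camera adjusted p = 0.609): SNAI2, a repressor of epithelial genes, fell at least 8.96-fold (log2 changes of -2.17, -1.84 and -1.92 without control array 1, 2 and 3, and 3.18-fold without background correction) while S100A4 and CDH2, N-cadherin (2.44-fold), rose. Proximal tubule genes gave 3 of 6 lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.238), with falls of MME (3.48-fold) and ANPEP (2.69-fold), both membrane peptidases. Of 6 measured leukocyte, endothelial and fibroblast markers, 2 were higher (CD14 and LUM) and 2 lower (PDGFRB and THY1), also adjusted over the list alone (camera adjusted p = 0.609).

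The interferon, NF-kB, antioxidant and hypoxia lists were not called by camera. Interferon-stimulated genes were higher in 10 of 26 cases and lower in 4, 10 and 5 adjusted over the list alone (camera adjusted p = 0.135), and BST2 rose 2.31-fold and IFIT2 2.05-fold. Among NF-kB targets and cytokines 4 of 15 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.751). CXCL8, a neutrophil chemokine, rose 4.69-fold, IL1A fell 3.51-fold and IL1B at least 2.96-fold. Without background correction these were 2.65-fold, 2.00-fold and 1.55-fold. The median of that list was above 0 and its mean and test below. Antioxidant and NRF2 targets gave 8 of 20 lower and 4 higher, 9 and 4 adjusted over the list alone (camera adjusted p = 0.332), with SOD2, the mitochondrial superoxide dismutase, lower by 2.01-fold and AKR1C3 higher. Hypoxia targets gave 5 of 16 lower and 4 higher, 7 and 5 adjusted over the list alone (camera adjusted p = 0.652), with LOX, lysyl oxidase, lower by 3.27-fold (1.90-fold without background correction) and DDIT4 higher by 2.00-fold.

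Of 17 p53 targets 4 rose and 2 fell, 5 and 2 adjusted over the list alone (camera adjusted p = 0.335), and TP53INP1 rose 3.10-fold while TIGAR fell 2.33-fold (1.39-fold without background correction). The endoplasmic reticulum chaperone list gave 3 of 17 lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.572). SDF2L1 and PDIA6 fell 1.62-fold and 1.61-fold, and the median of the list lay above 0 with its mean and test below. BCL2 family genes gave 2 of 14 lower and 2 higher, 2 and 1 adjusted over the list alone (camera adjusted p = 0.751), and BCL2L1, which encodes an inhibitor of apoptosis, fell 1.76-fold.

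**Figure D3:**
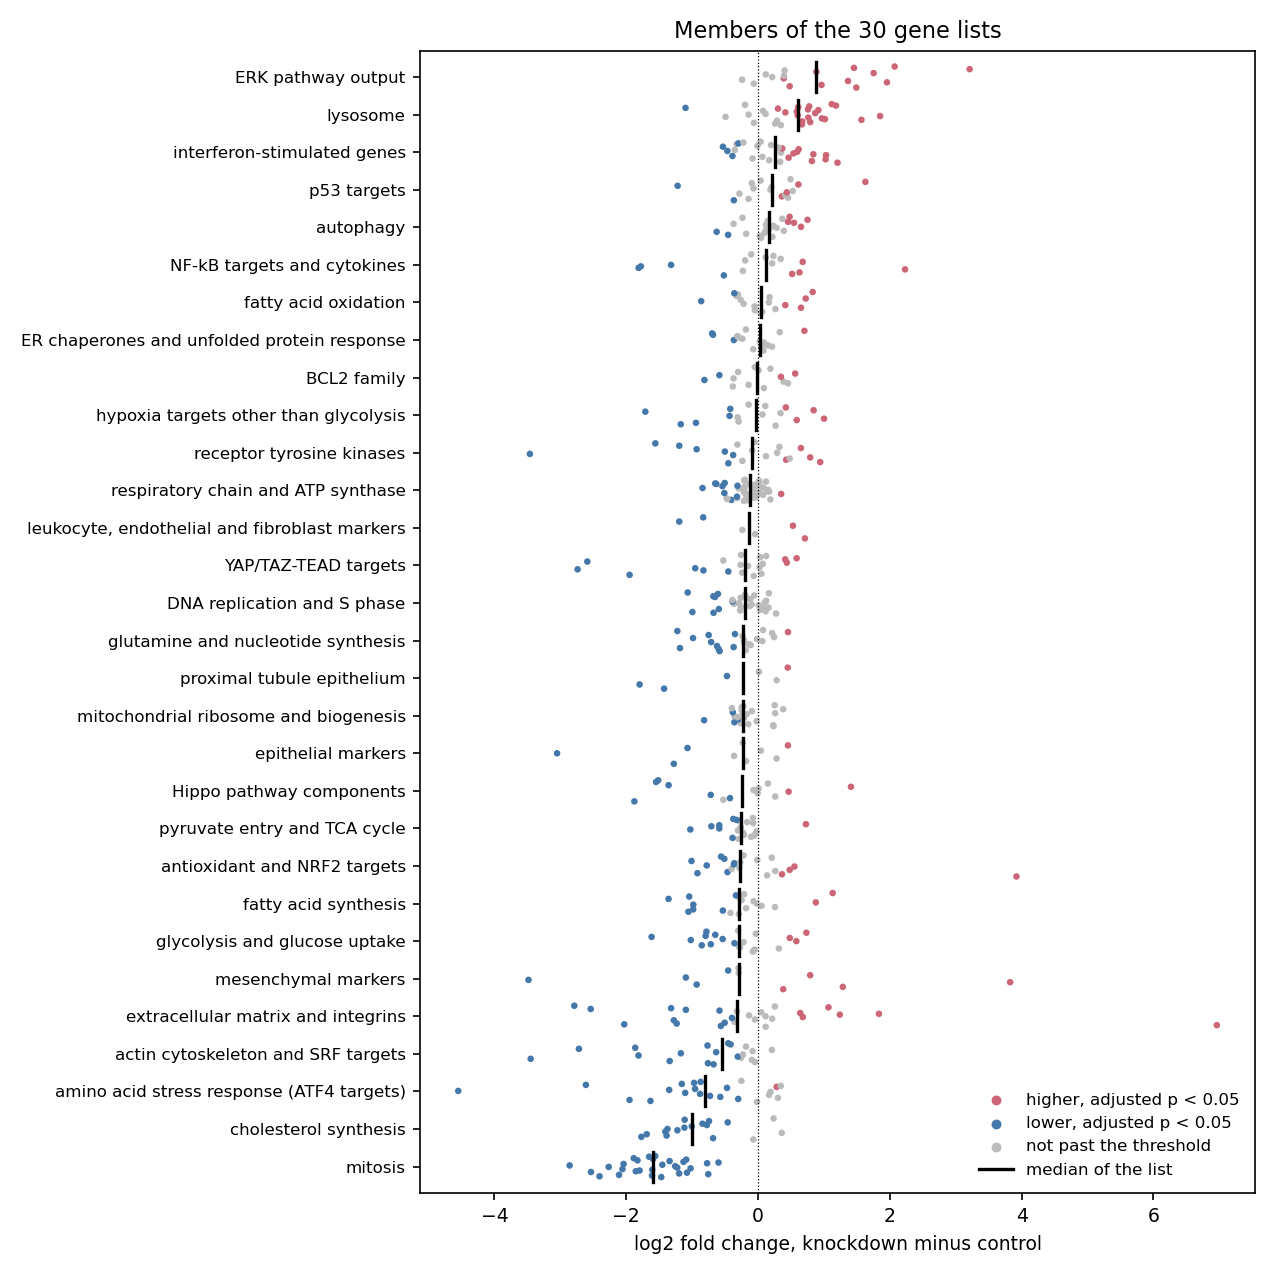
Log2 fold change, knockdown minus control, of each measured member of the 30 gene lists, which are ordered by their median (black ticks), with called rises in red, called falls in blue and other members in grey. The medians run from 0.89 for ERK pathway output to -1.59 for mitosis.

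In all, 11 of the 30 lists passed camera with the preset correlation, 2 higher and 9 lower. With an estimated correlation 0 passed camera in limma and 4 had an unadjusted p under 0.05, and fry called 17. The estimated correlations of ERK pathway output (-0.0203) and fatty acid synthesis (0.00936) lay below the preset 0.01, and both lists still lost their call. For these lists correlation between genes therefore does not account for the loss. How much of the loss correlation accounts for in the other lists was not tested. The count of 0 is thus no measure of what allowing for correlation costs by itself. Fry left out the lists of pyruvate and TCA and of the respiratory chain, and it added YAP/TAZ targets, Hippo components, epithelial markers, proximal tubule genes (adjusted p = 0.000171), receptor tyrosine kinases (0.0103), p53 targets (0.0219), NF-kB targets and cytokines (0.0217) and markers of other cell types (0.0265). Camera with the preset correlation also called up to 9 lists when the same 6 arrays were split in other ways. Those splits still carry part of the difference between the arms, so this count does not measure false calls.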

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

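The tests on other probes and on the direction of change among the largest changes, on the fibroblast markers, on array brightness, on replication genes and on other splits of the arrays were chosen only after the result was seen.

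Probes without a single gene symbol took no part in the comparisons by gene. Of 4855 such kept probes, 1068 (22%) changed between the arms, 461 higher and 607 lower, at an adjusted p under 0.05 in limma over all kept probes. The largest falls were at least 83.1-fold for ILMN_3237946, which was not detected on the knockdown arrays, and a log2 change of -4.31 for ILMN_1778087. The fitted change was at least 8-fold for 5 of the probes, and for 3 with probes not detected in an arm at their bound.

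The arrays numbered 1 stood apart from the other arrays of their arm in both arms: they were higher by at least 1 on the log2 scale for 178 genes and lower for 5, against 0 and 0 for the arrays numbered 2 and for those numbered 3. In the raw intensities the called probes stood above the other arrays by a median log2 ratio of 0.878 in the control arm and 1.73 in the knockdown arm. The bound of more than 1 in both arms, set in advance against the normalization, was missed. Raw intensities near equal in both arms, set in advance as the sign of the normalization as the cause, were not seen either. The values thus argue against the normalization as the whole cause, and a part owed to it stays open. Overall brightness is argued against, because the first array was the dimmest of the control arm (0.832 of the others' 75th percentile) and the brightest of the knockdown arm (1.23). The 97 other probes of the same genes shifted by a median of 0.0877, against 1.84 for the called probes of those genes. Signal of single probes, and not of transcripts, would give such a gap. The other probes are by rule dimmer than the called ones, which can also make a shift smaller, so the gap does not settle it. No biological explanation was tested, and 2 of the 178 genes, ABL2 and CD24, were called between the arms.

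Fitted changes of at least 8-fold were found for 11 genes higher and 27 lower, or 10 and 25 with genes not detected in an arm at their bound. For 15 of the 38 genes with such a fitted change another probe was kept, and 21 of the 22 other probes changed in the same direction, which argues against single probes as the whole cause there. Their median change of 1.72 was just short of 1.73, the bound first set for that test from the chosen probes' median of 3.46. The chosen probe is by rule the brightest of its gene. Some other probes lay near background, such as 1 of CALD1 (mean log2 intensity 4.65) and that of UBASH3B (4.75), where such a fall could hardly show. A part owed to single probes thus stays open, and the other 23 genes had no second probe. Fibroblasts among the knockdown cells as a candidate source of COL3A1 stay open: of 4 fibroblast genes only 1, LUM, was detected on no control array, and it rose at least 1.17-fold (not called with median scaling, adjusted p = 0.0535, the highest over its settings), whereas COL1A1, PDGFRB and THY1 fell from mean log2 intensities of 4.96, 9.28 and 9.92 in control cells, of which the last pair could hide a small share of fibroblasts. A difference between the lines that arose apart from the knockdown cannot be told apart from the knockdown itself, because each arm held 1 line, measured on technical repeats.

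All 30 measured mitosis genes fell, with a median log2 change of -1.59. Scaling of the arrays is argued against by the list's median, which stayed at -1.14 or below under 3 other background corrections and normalizations, past the bound of -1 set in advance. A replication list median of -0.197 lies between the values that an equal fall of all cell-cycle genes, or none outside mitosis, would give, and leaves open whether the cells may have cycled less. The knockdown is the biological difference that the design names, and it was not tested apart from the line.

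The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split was the only 1 of the 10 to reach its counts of 4638 changed genes and of 976 changed by at least 1 on the log2 scale, and the highest count of the other splits was 0 for both. For the gene lists the real split gave 11 and the highest of the others 9. Camera with the preset correlation thus called lists in splits with 0 changed genes. Those splits still carry part of the difference between the arms, so their list counts do not measure false calls. Of the 9 other splits, 3 part the 3 same-numbered pairs as the real split does, and these gave 6 to 9 lists. The remaining splits part 1 pair and gave 1 to 9.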

How the results depend on the processing

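Leaving out both arrays numbered 1 was chosen only after the data were seen, and the other settings in advance. YAP1 stayed lower and past the threshold in all 17 settings, with log2 changes of -1.75 to -1.08 and adjusted p-values of 1.1e-05 to 0.00328 in limma. The count of changed genes ran from 3363 (without control array 3) to 5624 (replicate number as a block), and with each kept probe by itself 6576 of 20348 probes changed. Genes changed by at least 1 on the log2 scale numbered 378 (162 higher and 216 lower) without background correction and 511 (221 and 290) with normexp on the intensities alone. Both settings kept quantile normalization, and median scaling after the planned background correction gave 964. The drop thus goes with the background step. Changed genes of any size numbered 4556 without background correction and 4644 with normexp on the intensities alone, against 4638. The fitted folds thus shrank while the number of calls hardly moved, and why they shrank was not tested. With the replicate number as a block 5624 genes changed, 3002 higher and 2622 lower, among them all 4638 of the fit without it, and the pairing changed no list call but that of DNA replication. Without both arrays numbered 1, 4594 genes changed, 881 by at least 1 on the log2 scale, and 9 lists passed, without those of pyruvate entry and the TCA cycle and of the respiratory chain.

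Lists past the threshold numbered 0 with an estimated correlation and 17 with fry, which asks another question, and 7 of the 11 kept their call in every setting with a preset correlation. Named genes kept direction and call in 2215 of 2284 values, lost the call in 67 and reversed in 2, and 122 of the 138 lost it in no setting that gave them a value. For 20 of the 138 some settings gave none, down to 12 of 17, because their probe left the filter, and 107 kept the call in all 17. The reversals were of CALD1, at 0.01775 without control array 2 and 0.04069 without control array 3, against -3.512 at the other end of the range (without knockdown array 3), because its chosen probe, detected on the 3 control arrays only, then left the filter. Signal over background limits genes that were not detected in an arm to a bound. Slide as a block was not run, since no slide is named.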

Other observations

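The gene groups in this part were put together, and their values tested in limma, after the results were seen, and no group was tested for enrichment.

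Of 11 measured genes of antigen presentation by MHC class II 9 fell and 0 rose in the knockdown arm, with a median log2 change of -1.40. HLA-DRA, the alpha chain of HLA-DR, fell by 2.33 ± 0.16 (SE, adjusted p = 1.12e-05), HLA-DPA1 by 2.15 ± 0.18 (adjusted p = 4.09e-05) and CD74, the chaperone of class II molecules, by 1.82 ± 0.22 (adjusted p = 0.00026). HLA-DMA (log2 change -0.40) and HLA-DOA (0.17) did not pass the threshold. Of the 9 falls 5 were of HLA-DRB genes, which are near-identical copies, so their probes cannot be assigned to 1 gene with certainty. Of 9 genes of class I presentation, 3 rose, among them TAPBP (log2 change 1.07), and 0 fell. The medians stayed below 0 for class II (-1.41 to -0.584) and above 0 for class I (0.246 to 0.281) under 3 other background corrections and normalizations.

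Lysosomal enzymes outside the list fixed in advance were higher in 19 of 39 cases and lower in 5. CTSF, cathepsin F, rose by 2.58 ± 0.13 (SE, adjusted p = 2.76e-06), IDUA, alpha-iduronidase, by 2.10 ± 0.13 (adjusted p = 8.32e-06) and MANBA, beta-mannosidase, by 2.02 ± 0.14 (adjusted p = 1.21e-05), whereas CTSV, cathepsin V, fell by 2.03 ± 0.15 (adjusted p = 1.9e-05) and CTSH, cathepsin H, by 1.46 ± 0.10 (adjusted p = 1.39e-05). Of 21 genes of adhesion, guidance and signalling in the nervous system 13 rose and 5 fell, against 39.8% called over all genes. Several of the 21, such as CTNND2, NCAM2 and GABBR2, were among the largest changes of all genes. The share called thus cannot stand for such genes in general. CTNND2, delta-catenin, had a log2 change of 2.79, NCAM2, a neural adhesion molecule, of 2.59 and SEMA3A, a secreted guidance cue, of 2.39, each with an adjusted p under 0.05, while the falls were GABBR2, a GABA receptor subunit (log2 change -3.06), ASIC2 (-2.34), KCNS1 (-2.31), KCNMB4 (-2.07) and EFNB2 (at least 1.59-fold, to below background). None of the called members of these groups changed sign under the 3 other corrections and normalizations. PPARG, a transcription factor of fat storage, had a log2 change of -3.31 ± 0.12 (SE, adjusted p = 5.64e-07), and ANGPTL4, a gene it is known to induce, had one of 2.83 ± 0.12 (adjusted p = 1.25e-06).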
